A study of Mus musculus with 4 samples.

How the data were processed

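The series measured total RNA from mouse embryonic stem cells on 4 Affymetrix arrays, and 1 table of deposited values covering all 4 arrays was used here. The cells were E14tg2a, a line grown without a feeder layer, labelled either as controls (called control cells) or as expressing a constitutively active form of the kinase Akt (called Akt cells). The titles call the Akt cells Akt12. Whether 12 is the number of a clone is not given in the sources used here, and a difference of one clone from its parent line would enter every Akt against control value. Whether the control cells carry an empty vector is not given in the sources used here. Each was sampled once with leukemia inhibitory factor (LIF) at 3000 U/ml and once after 4 days without it. The 4 groups therefore hold 1 array each, and no label describes a second culture or a second clone of any group.

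The deposited values are intensities on a linear scale, 1 per probe set, with 1 decimal and no negative value. The software that made them, its version, and any scaling are not given in the sources used here. The values looked unscaled, because the 2% trimmed means were 121, 97.4, 81.7 and 80.3 for control cells with LIF, control cells without LIF, Akt cells with LIF and Akt cells without LIF. The highest was 1.51 times the lowest, beyond the 10% difference set before the data were examined as the limit for using values as deposited. The intensities of the 12422 probe sets that are not array controls were therefore quantile normalized with limma 3.58.1 in R 4.3.3. Quantile normalization gives every array the same distribution, so a shift common to most genes of an array would be removed. Values under the 40th percentile of all values, an intensity of 15.8, were set to that floor, and log2 was taken. No intensity of the 19 probe sets for transcripts absent from mouse cells exceeded 14.9 as deposited.

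Of 12488 probe sets, 66 were array controls. Among the other 12422, the platform annotation paired 10833 with 1 gene symbol, 396 with several and 1193 with none. Symbols were updated through gene identifiers in a RefSeq table of assembly GRCm38.p6, which held 10817 of the 10833. That table was used for names and for which genes share a chromosome, and no coordinates are printed because a genome build is not given in the sources used here. Of the 8251 genes, 2073 had several probe sets, and the probe set with the highest mean log2 value over the 4 arrays stood for the gene. At this floor, 6258 genes were above it on at least 1 array and 5027 on all 4.

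With 1 array per group, no test within a comparison is possible. For each of the 4 comparisons, genes above the floor on at least 1 of the 2 arrays were counted as different when the log2 difference was at least 1 in size, which is 2-fold. A gene at the floor on 1 array has only a bound, written as at least N-fold. The 20 gene lists were fixed before the data were examined. They cover pluripotency, LIF-STAT3 targets, primitive and visceral endoderm, epiblast, primitive streak and mesoderm, neuroectoderm, trophoblast, FOXO targets, PI3K-AKT components, glycolysis, sterol and fatty acid synthesis, Wnt-beta-catenin targets, BMP targets, ERK targets, cell cycle, stress response, fibroblast and feeder markers, imprinted genes, Y chromosome and ribosomal proteins. For each list, the median log2 difference of its measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these arrays and is not a p-value. A median outside the central 95% of the random lists is described as outside the range of the random lists.

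What both lines or both media share was fitted with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over 6258 genes, adjusted p threshold 0.05). The model held a term for the line and a term for LIF, leaving 1 residual degree of freedom per gene, to which eBayes added 8.69 prior degrees of freedom. In that model the difference between the lines' responses serves as the error. Its p-values measure the spread between these 4 arrays, and nothing in the labels says how far separate cultures would differ. The spread between probe sets of one gene was the other error estimate, and it covers differences between probe sets, not between cultures. The number of arrays limits the precision of every value.

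The steps were tested on simulated data. For LIF withdrawal over both lines, limma recovered 31% of 100 genes simulated with a 2-fold difference and 87% of 100 with a 4-fold difference, and called 1 of 6058 unchanged genes. For LIF withdrawal in control cells, the 2-fold count took in 54% of 100 genes simulated at 2-fold and 89% of 100 at 4-fold. Of 200 lists of 30 random genes, 6% fell outside the range of the random lists, and 100% of 200 lists simulated 2-fold lower did. The noise in these simulations was that of the closest pair of arrays. For limma, both lines were given the same effect, so their responses differed only by that noise. On the real arrays any further difference between the responses adds to the error, so the limma rates may not hold there.

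Genes were named by a rule fixed before the data were examined, and not every gene that it takes is printed. It takes Akt1 and 13 markers whatever their value, the 8 genes most different in each direction among those above the floor on both arrays, and up to 4 members of each list among those at least 2-fold different. It also takes the 4 largest bounds in each direction, the 8 genes each way whose responses differ most between the lines among those above the floor on all 4 arrays, and the 8 genes each way with the smallest adjusted p in each limma fit. Exceptions are named as such. The marker T was not among the genes measured here. Probe sets without 1 gene were counted and not named.

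Alternatives planned beforehand were scaling to equal 2% trimmed means, centring on the median log2 difference, floors at the 25th and 60th percentiles, log2(value + 32) with no floor or filter, the mean of all probe sets of a gene, and only probe sets with a plain _at suffix. For limma they also included eBayes with a trend and models without the second term. Scaling to the 9 probe sets of the bacterial hybridization controls was added after seeing the data. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.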

Results

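The arrays compared mouse embryonic stem cells with and without active Akt, in the presence and absence of LIF. LIF is the cytokine that keeps mouse embryonic stem cells undifferentiated in culture through STAT3, and Akt is a kinase that acts downstream of phosphoinositide 3-kinase. The series title asks what LIF does in cells that overexpress Akt. The 4 arrays measured 5625 to 5659 genes above the floor, between 68.2% and 68.6% of the genes. No group has a replicate, so none of the differences between single arrays has a replicate check. The actin 3' to 5' signal ratio, a measure of RNA integrity and labelling, was 2.33 in control cells with LIF, 1.66 in control cells without LIF, 3.04 in Akt cells with LIF and 2.48 in Akt cells without LIF. The Gapdh ratio was 3.03, 3.19, 3.05 and 2.46 in the same order.

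The array of control cells without LIF stood furthest from the others. Over 5027 genes above the floor on all 4 arrays, the SD of the log2 differences between control cells with and without LIF was 0.714, and between Akt cells with and without LIF it was 0.512. The closest pair was control cells with LIF and Akt cells without LIF, with an SD of 0.408 and 223 genes at least 2-fold different. The most distant pair was control cells without LIF and Akt cells with LIF, with an SD of 0.871 and 1130 such genes. The actin ratios were 2.33 and 2.48 in the closest pair and 1.66 and 3.04 in the most distant pair. The Gapdh ratios did not follow that order, at 3.03 and 2.46 against 3.19 and 3.05. A part of RNA quality in these distances cannot be told apart from that of the line or LIF. Log2 differences of probe sets of the same gene spread around the mean of that gene with an SD of 0.411 after LIF withdrawal in control cells and 0.351 in Akt cells.

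LIF withdrawal in control cells was accompanied by lower levels of most pluripotency genes. Of 30 measured members of that list, 22 were at least 2-fold lower, none was 2-fold higher and 8 lay between, with a median log2 difference of -1.85, below all 10000 random lists. Zfp42, a zinc finger gene expressed in undifferentiated stem cells, went from an intensity of 1219.1 to 82.4, which is 14.8-fold lower. Fbxo15 was 19.6-fold lower, Nr5a2 was 6.67-fold lower, and the nuclear receptor gene Nr0b1 was at least 20.9-fold lower. A second probe set of Nr5a2 had a log2 difference of -0.09. Sox2 was 4.74-fold lower and Klf4 6.58-fold lower. Pou5f1 and Nanog, which encode core transcription factors of pluripotency, had smaller log2 differences of -0.90 and -0.92. With a floor at the 60th percentile the median of the list was -1.25.

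Socs3, the feedback inhibitor that STAT3 induces, was 5.17-fold lower in control cells without LIF, while Stat3 itself had a log2 difference of -0.18. A second probe set of Stat3 gave -1.07. Among 20 LIF-STAT3 targets, 6 were at least 2-fold lower and 2 higher, with a median of -0.16 that lay within the range of the random lists. Gbx2 was at least 4.43-fold lower, and the immediate early gene Fos was 4.13-fold higher.

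Genes of several differentiated lineages were higher in control cells after LIF withdrawal. Of 14 trophoblast genes, 6 were at least 2-fold higher and none lower, with a median of 0.79, above all 10000 random lists. The members most different were the keratin genes Krt19, Krt8 and Krt18 (5.4-fold, 4.91-fold and 4.75-fold higher) and the transcription factor gene Tfap2a (5.11-fold). Of 23 primitive streak and mesoderm genes, 8 were higher and none lower, with a median of 0.73. They included Wnt3 (5.01-fold), cardiac actin Actc1 (5.6-fold), the smooth muscle gene Tagln (4.83-fold) and Evx1 (at least 7.73-fold). The 16 fibroblast and feeder markers had 3 members at least 2-fold higher and a median of 0.40 on the same array. Those were the matrix genes Dcn (9.2-fold), Col3a1 (at least 4.54-fold) and Col1a1 (2.39-fold).

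Of 20 primitive and visceral endoderm genes, 7 were at least 2-fold higher and 1 lower in control cells without LIF, with a median of 0.43. Cited1 was 5.68-fold higher and Dab2 5.51-fold higher, though a second probe set of Dab2 had a log2 difference of 0.30. Gata4, an endoderm transcription factor gene, was at least 3.5-fold higher, and the laminin gene Lama1 at least 3.26-fold lower. Gata6, Fgf5 and Sox1 were at the floor on both arrays, and Cdx2 was above it only without LIF at 17.9. The 9 epiblast genes went both ways, with Cdh2 and Sox4 higher (3.18-fold and 2.81-fold) and Dnmt3a and Pim2 lower (5.64-fold and 3.99-fold). Their median was 0.01 and their mean -0.10. Of 15 neuroectoderm genes, 3 were at least 2-fold lower and 1 higher. Their median was -0.40, below the range of the random lists, with Sox3 3.88-fold higher and En2 3.31-fold lower.

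Among signalling and metabolic groups, 4 of 10 BMP targets were at least 2-fold higher in control cells without LIF and none lower, with a median of 0.51. They were Hes1 (10.9-fold), Msx2 (at least 6.5-fold), Msx1 (5.43-fold) and the inhibitory Smad gene Smad6 (2.58-fold). Imprinted genes were higher in 7 of 15 cases, with a median of 0.97, among them Peg3 (4.7-fold) and the growth factor gene Igf2 (3.89-fold). Wnt-beta-catenin targets had a median of 0.68 over 8 genes, which turned to -0.09 with a floor at the 60th percentile. Of 17 glycolysis genes, 3 were lower and 1 higher, with a median of -0.49. The phosphofructokinase gene Pfkp was 6.76-fold lower and the glucose transporter gene Slc2a3 2.85-fold higher. Medians lay within the range of the random lists for cell cycle genes (-0.29), stress response genes (-0.06), ERK targets (0.13), FOXO targets (0.01), PI3K-AKT components (-0.27), sterol and fatty acid synthesis genes (0.14) and ribosomal proteins (-0.11). All of these lists but the last had members at least 2-fold different. Higher were Atf3 (4.94-fold), Phlda1 (4.14-fold), Dusp1 (2.46-fold), Gadd45b (4.25-fold), Irs2 (3.23-fold) and Klf6 (3.01-fold). Lower were Bnip3 (3.9-fold), Hsph1 (2.22-fold), Sod2 (3.12-fold), Ccne1 (2.29-fold), Acly (2.02-fold), Akt2 (at least 2.13-fold) and the phosphatase gene Inpp5d (at least 4.82-fold, with another probe set at 1.06 in log2).

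Across all genes, 442 were at least 2-fold higher and 383 lower in control cells after LIF withdrawal, out of 5984 above the floor on at least 1 of the 2 arrays. The 8 most different upward were Tgfb1 (20.6-fold), Wnt6 (15.6-fold), Acta1 (11.2-fold), Hes1 (10.9-fold), the Wnt secretion factor gene Wls (10.4-fold), Dcn (9.2-fold), Sprr2b (8.16-fold) and the interferon-inducible Gbp2b (8.02-fold). Downward, after Fbxo15 and Zfp42, they were the hedgehog receptor gene Ptch1 (19.6-fold), Aass (17.6-fold), Gsta4 (13.9-fold), the metallothionein gene Mt1 (12.7-fold), Rpl39l (8.56-fold) and Twf2 (8.43-fold). The second probe set of Ptch1 had a log2 difference of 0.06. Tmprss2 (at least 18.3-fold), Wnt4 (at least 14.2-fold), Mmp9 (at least 7.85-fold) and Cxcl10 (at least 7.81-fold) were above the floor only without LIF. Calcoco2 (at least 10.9-fold), Pipox (at least 7.27-fold) and Cbr3 (at least 6.22-fold) were above it only with LIF.

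**Figure D1:**
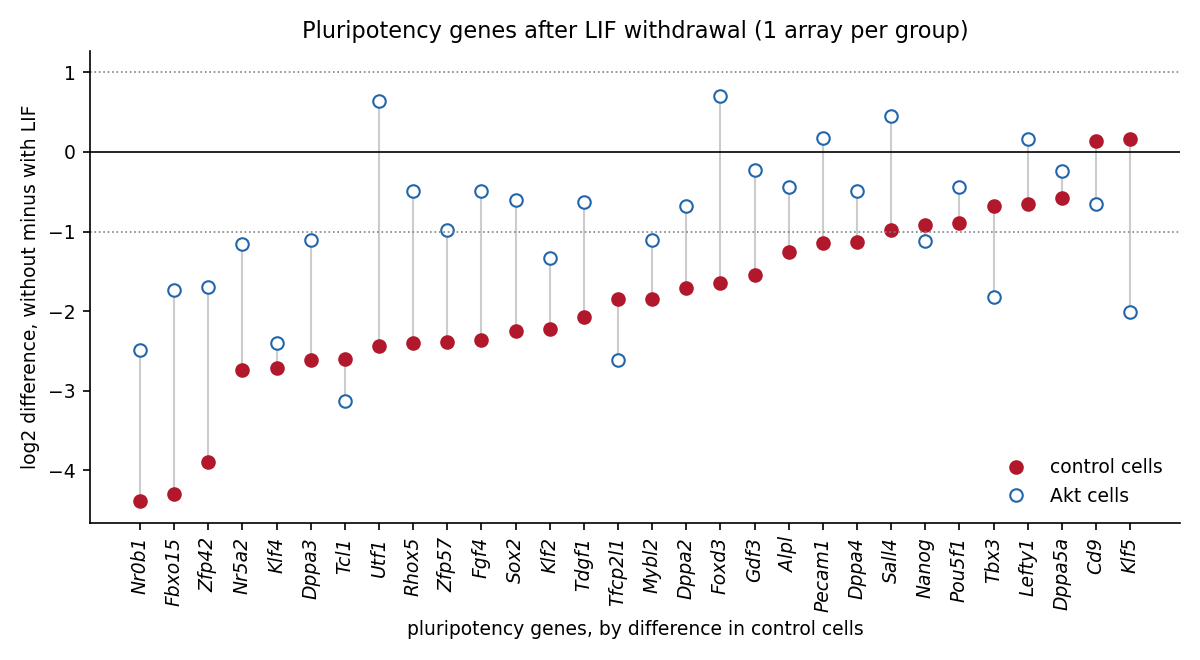
Log2 difference in array intensity (without minus with LIF, 1 array per group) of the 30 measured pluripotency genes in control cells (filled) and Akt cells (open), with dotted lines at 2-fold. Grey lines join the 2 values of a gene, a gene at the floor on 1 array is shown at its bound, and 22 genes in control cells and 13 in Akt cells lie at or under the lower dotted line.

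In Akt cells the pluripotency genes were also lower without LIF, by less for most of them. Of the 30 genes, 13 were at least 2-fold lower and none higher, with a median of -0.66, again below all 10000 random lists. Zfp42 was 3.23-fold lower, at 552.8 against 1784.5 with LIF. Sox2 had a log2 difference of -0.60 and Pou5f1 of -0.44, while Nanog was 2.16-fold lower. The members most different were Tcl1, which encodes a coactivator of Akt (8.74-fold lower), Tfcp2l1 (6.1-fold), Nr0b1 (5.59-fold) and Klf4 (5.29-fold). A second probe set of Tfcp2l1 had a log2 difference of -0.79.

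The LIF-STAT3 targets were lower in Akt cells without LIF in 7 of 20 cases and 2-fold higher in none, with a median of -0.46, below all random lists. Socs3 was 7.42-fold lower and Bcl3 at least 8.1-fold lower. The 9 epiblast genes had a median of 1.15, above all random lists, with 5 at least 2-fold higher and none lower. Those 5 included the kinase gene Pim2 (5.82-fold), Zic2 (3.02-fold), the DNA methyltransferase gene Dnmt3a (2.69-fold) and Pou3f1 (at least 2.58-fold). A second probe set of Zic2 went the other way, with a log2 difference of -0.43. Fgf5 was at the floor on both arrays.

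In Akt cells without LIF, 4 of 23 primitive streak and mesoderm genes were at least 2-fold higher and 1 lower, with a median of 0.32. Acta2 (at least 4.37-fold), Wnt3 (4.33-fold) and Tagln (3.93-fold) were higher, and Bmp4 was 4.18-fold lower. Only Krt18 among 14 trophoblast genes was 2-fold higher (2.46-fold), with a median of 0.48 for the list. Of 20 endoderm genes, 2 were higher and 2 lower, and the median of -0.07 changed sign with the scaling. Dab2 was 3.75-fold higher and Apoe 2.97-fold lower. Gata4 had a log2 difference of -0.31 and Gata6 of -0.67. The fibroblast and feeder markers had no member 2-fold different and a median of 0.04, which was -0.004 when scaled to the hybridization controls. Of these markers, Dcn and Col3a1 were at the floor on both Akt arrays and could not show a difference. The 15 neuroectoderm genes had 2 higher and 3 lower and a median of 0.00, among them Gap43 (2.91-fold higher) and Mapt (6.73-fold lower, with a second probe set at -0.14).

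Sterol and fatty acid synthesis genes had a median of 0.56 in Akt cells without LIF, above all random lists, and 17 of 19 were above 0. Dhcr7 (2.56-fold), Hmgcs1 (2.43-fold) and Msmo1 (2.07-fold), which encode enzymes of the cholesterol pathway, were at least 2-fold higher. BMP targets had a median of 0.75, with Id3 (4.02-fold) and Id1 (2.17-fold) higher. Wnt-beta-catenin targets had a median of 0.70 with no member 2-fold different. Imprinted genes had a median of 0.37 with Peg3 (2.75-fold) and Ndn (2.28-fold) higher. Stress response genes had a median of -0.24, below the range of the random lists, with 5 of 21 at least 2-fold lower and 1 higher. They included Atf5 (7.13-fold), Trib3 (6.63-fold), Ddit3 (at least 5.2-fold) and Herpud1 (2.38-fold). FOXO targets had a median of -0.28, below that range, with 2 of 16 at least 2-fold lower and 1 higher. They were Sod2 (2.25-fold lower), Gadd45b (2.23-fold higher) and Txnip (2.07-fold lower), whose plain _at probe set gave 0.59. Scaled to the hybridization controls, the medians in Akt cells were 0.17 for imprinted genes, 0.17 for mesoderm, 0.32 for trophoblast and 0.35 for sterol and fatty acid synthesis, and -0.91 for pluripotency, -0.65 for LIF-STAT3 targets, -0.46 for stress response genes and -0.41 for FOXO targets.

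Across all genes in Akt cells, 179 were at least 2-fold higher and 217 lower without LIF, out of 5945. Higher were the potassium channel gene Kcnk1 (8.26-fold), Prom1 (7.47-fold), Pim2, Acta1 (5.45-fold), Pus1 (4.4-fold), Amot (4.37-fold), Wnt3 and the hyaluronan synthase gene Has2 (4.11-fold). Lower were Nupr1 (12.9-fold), Tcl1, Zap70 (7.64-fold), Socs3, Atf5, Mapt, Trib3 and Pfkp (6.6-fold). Scaling to the hybridization controls moved the share of higher genes among those 2-fold different from 45.2% to 24.6%, as it shifted the median log2 difference of all genes to -0.17.

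The responses of the lines were compared directly. The count of genes at least 2-fold different was 825 in control cells and 396 in Akt cells. With no effect simulated in 6258 genes, the spread of the closest pair of arrays gave 97 and 91 such genes for these comparisons. That pair itself had 223 such genes, so this simulation, with normally distributed noise, gave fewer than the arrays it was drawn from. Its counts are therefore too low to serve as an expectation. A second simulation took its noise from the probe sets of one gene and gave 555 and 545 genes. That noise was pooled over the 4 comparisons, so it also held differences between comparisons. The counts of this second simulation are therefore too high to serve as an expectation. Neither simulation covers how far separate cultures would differ. Of the 30 pluripotency genes, 24 had a less negative or more positive difference in Akt cells than in control cells, 23 were lower in both lines and 10 were at least 2-fold lower in both. The median of their response in Akt cells minus that in control cells was 1.17, above all random lists, and 0.49 with a floor at the 60th percentile. The same median was -0.56 for LIF-STAT3 targets, -0.54 for endoderm, -0.45 for trophoblast, -0.56 for FOXO targets, -0.38 for imprinted genes and -0.42 for stress response genes, each below the range of the random lists. It was 0.57 for glycolysis and 0.55 for sterol and fatty acid synthesis, above that range. The difference between the lines was not tested, since it has no residual error with 4 arrays.

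Among 5671 genes above the floor on at least 1 array of each line, 46 were 2-fold higher in both, out of 376 in control and 175 in Akt cells, where independent lists would share 11.6. For lower genes, 54 were shared out of 380 and 206, where independent lists would share 13.8. Read one way, 12.2% of the genes higher in control cells were also higher in Akt cells, and read the other way 26.3%. The log2 differences of the lines had a Pearson correlation of 0.194 across 5027 genes (Spearman 0.125), and genes are not independent replicates. Among the 5027 genes above the floor on all 4 arrays, 106 were at least 2-fold different in both lines, of which 79 went in the same direction and 27 in opposite directions. How many independent lists would give in opposite directions was not worked out. In the same 5027 genes, those whose response in Akt cells was furthest above that of control cells were Ptch1 (log2 4.93), Pim2 (4.54), Slc27a2 (4.06), Dnmt3a (3.92), Gsta4 (3.72), Utp14a (3.57), Mt1 (3.45) and Twf2 (3.29). Those furthest below were Lgals3 (-3.52), Kdelr3 (-3.45), Hmga2 (-3.41), Bmp4 (-3.21), Wls (-3.15), Hes1 (-3.11), Lpp (-3.10) and Litaf (-3.09). Genes at the floor on some arrays, which have only bounds, are not in that ranking.

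**Figure D2:**
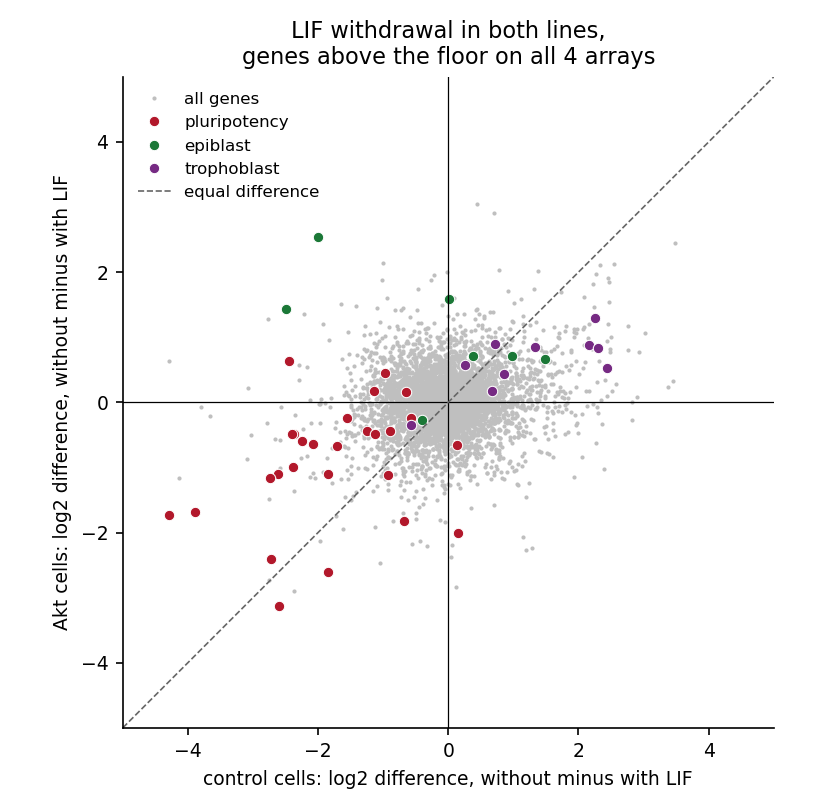
Log2 difference after LIF withdrawal in control cells (horizontal) and Akt cells (vertical) for the 5027 genes above the floor on all 4 arrays, with genes of 3 lists in colour and a dashed line of equal difference. Most pluripotency genes lie left of 0 and above the dashed line, and Pim2 and Dnmt3a lie in the upper left.

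Akt cells with LIF were compared with control cells with LIF, which asks how the lines differ before LIF is removed. This comparison shares the array of Akt cells with LIF with that of LIF withdrawal in Akt cells, so the 2 are not independent. Medians after withdrawal and here had opposite signs for epiblast (1.15 and -0.60), BMP targets (0.75 and -0.51) and stress response genes (-0.24 and 0.58). Those of imprinted genes did not (0.37 and 0.26). Opposite values of that kind could come from the shared array alone. Akt1 itself had a log2 difference of -0.13 with LIF and -0.65 without. The labels do not say which Akt form or species was expressed, and the probe set may lie outside the introduced sequence, so this does not check the label. Of the 30 pluripotency genes, 5 were at least 2-fold higher and 2 lower. Their median was 0.18, above the range of the random lists (-0.19 to 0.17), with 21 above 0, and it was 0.33 when scaled to the hybridization controls. Pou5f1 had a log2 difference of 0.32, Nanog 0.08, Sox2 0.06, Klf4 0.13 and Zfp42 0.55. A second probe set of Pou5f1 gave -0.38 and a second one of Nanog -0.05. Nr0b1 (2.8-fold) and Tbx3 (2.6-fold) were higher, and Foxd3 (at least 3.14-fold) and Dppa3 (2.65-fold) lower.

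Endoderm genes were higher in Akt cells with LIF in 9 of 20 cases and 2-fold lower in none, with a median of 0.94, above all random lists. With a floor at the 25th percentile the median was 0.23. Pdgfra (at least 4.71-fold), Gata4 (at least 3.74-fold), Sox17 (at least 3.57-fold) and Cubn (at least 4.97-fold) were above the floor in Akt cells and not in control cells. The plain _at probe set of Cubn went the other way, at -0.12. Stress response genes were 2-fold higher in 7 of 21 cases, with a median of 0.58, above all random lists. They included the transcription factor genes Atf5 (7.42-fold) and Ddit3 (at least 5.2-fold), the pseudokinase gene Trib3 (6.01-fold) and Mdm2 (2.59-fold). FOXO targets had a median of 0.28, above the range of the random lists, although none was 2-fold higher and Gadd45b (3.34-fold) and Irs2 (at least 2.71-fold) were lower.

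Several groups were lower in Akt cells with LIF. BMP targets had a median of -0.51, with Id3 (2.85-fold), Id1 (2.7-fold) and Id2 (2.37-fold) lower. Epiblast genes had a median of -0.60, with Cdh2 (at least 5.46-fold), Pim2 (4-fold) and Pou3f1 (at least 2.28-fold) lower. Primitive streak and mesoderm genes had a median of -0.20, with the smooth muscle genes Tagln (13.5-fold), Acta2 (at least 13.4-fold) and Cnn1 (at least 2.42-fold) lower and 2 members higher. That median was -0.09 when scaled to the hybridization controls. Sterol and fatty acid synthesis genes had a median of -0.27 and imprinted genes of 0.26, each outside the range of the random lists, and -0.17 and 0.38 under that scaling. Of 3 measured Y chromosome genes, Eif2s3y was 8.16-fold lower and Uty at least 2.35-fold lower. Medians lay within that range for the LIF-STAT3 targets (-0.09, mean 0.11, with Fos 4.79-fold and Icam1 2.94-fold higher), neuroectoderm (-0.15), trophoblast (0.01, mean -0.10), PI3K-AKT components (-0.13), glycolysis (-0.14), Wnt-beta-catenin targets (-0.10), ERK targets (0.14), cell cycle (-0.04), fibroblast and feeder markers (0.00) and ribosomal proteins (0.01). Among the PI3K-AKT components, Inpp5d was 2.65-fold higher, and Pik3r2 (at least 2.99-fold) and Akt2 (at least 2.13-fold) were lower. Dll1 was 3.96-fold higher and Nes 2.89-fold lower among neuroectoderm genes, Plac1 2.54-fold higher among trophoblast genes, and Myc (2.45-fold), Ccne1 (2.37-fold) and Ccn2 (2.31-fold) were lower.

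In all, 208 genes were at least 2-fold higher and 216 lower in Akt cells with LIF, out of 5938. With no effect simulated in 6258 genes, the spread of the closest pair of arrays gave 89, while that pair itself had 223. Higher were Kdelr3 (7.48-fold), Atf5, Traf3ip2 (6.33-fold), Trib3, Cebpb (5.45-fold), Adgrd1 (5.45-fold), Aard (5.43-fold) and Fos. Nupr1 (at least 16-fold) and Ephx1 (at least 7.02-fold) were above the floor only in Akt cells. Lower, after Tagln and Eif2s3y, were Kcnk1 (11.9-fold), Anxa3 (9.58-fold), Slc27a2 (8.82-fold), Pus1 (7.7-fold), Acta1 (6.15-fold) and Cnn2 (5.07-fold). Nexmif (at least 5.83-fold) and Gbp2b (at least 5.23-fold) were above the floor only in control cells. Scaling to the hybridization controls shifted the median log2 difference of all genes to 0.13 and the share of higher genes from 49.1% to 63.3%.

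Without LIF the lines differed in more genes. This comparison shares the array of control cells without LIF with that of LIF withdrawal in control cells, so the 2 are not independent. Akt cells had higher levels of pluripotency genes, 16 of 30 at least 2-fold higher and 1 lower, with a median of 1.04, above all random lists. Nr0b1 (at least 10.5-fold), Rhox5 (8.43-fold), Zfp42 (6.71-fold), Fbxo15 (6.4-fold) and Sox2 (3.26-fold) were higher. Pou5f1 had a log2 difference of 0.78, Klf4 of 0.44 and Nanog of -0.11, while a second probe set of Nanog gave 0.32. Socs3 was 2.07-fold lower, and the 20 LIF-STAT3 targets had a median of -0.46, with 8 lower and 3 higher. Glycolysis genes had a median of 0.46, above the range of the random lists, with Pfkp (2.31-fold) and Pdk1 (2.29-fold) higher and Slc2a3 (4.4-fold) lower.

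Mesoderm, trophoblast and BMP target genes were lower in Akt cells without LIF than in control cells without LIF. Mesoderm genes were 2-fold lower in 10 of 23 cases and higher in 1, with a median of -0.53, led by Tagln (16.6-fold), Acta2 (13.1-fold), Evx1 (at least 7.73-fold) and Bmp4 (6.28-fold). Trophoblast genes were lower in 6 of 14 cases with a median of -0.59, led by Krt19 (6.46-fold) and Tfap2a (at least 5.64-fold). BMP targets were lower in 6 of 10 cases with a median of -1.14, led by Msx1 (5.33-fold) and Hes1 (4.44-fold). In the fibroblast and feeder list, 4 of 16 were lower with a median of -0.28, within the range of the random lists, including Dcn (at least 9.69-fold) and Fn1 (2.1-fold). Endoderm genes had 3 higher and 2 lower and a median of -0.01 against a mean of 0.17. Epiblast genes had 2 higher and 2 lower and a median of 0.49, within the range of the random lists, with Dnmt3a 9.38-fold higher and Cdh2 7.8-fold lower. The 15 neuroectoderm genes had 2 higher and 2 lower and a median of 0.12, also within that range. Other lists within it had members that differed, among them Phlda1 (5.8-fold lower), Gadd45b (6.39-fold lower), Dusp6 (2.75-fold lower), Atf3 (2.9-fold lower), Bnip3 (3.38-fold higher) and Inpp5d (at least 5.3-fold higher, with another probe set at -0.07 in log2).

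Across all genes, 353 were at least 2-fold higher and 488 lower in Akt cells without LIF, out of 6009. The closest-pair simulation gave 90 genes, and the closest pair itself had 223. Mt1 was 42.7-fold higher, Mt2 10.6-fold, Ptch1 14.4-fold (second probe set 0.08 in log2), Gsta4 12-fold, Rpl39l 10.3-fold, Chchd10 9.32-fold and Cpt1a, the rate-limiting enzyme of mitochondrial fatty acid import, 8.49-fold. Lower, besides Tagln and Acta2, were Wls (15.1-fold), Phldb2 (14.4-fold), Anxa3 (12.7-fold), Acta1 (12.6-fold), Wnt6 (12.1-fold) and Csf1 (10.7-fold). Gbp2b (at least 42-fold), Gbp2 (at least 32.8-fold), Tgfb1 (at least 20.9-fold) and Tmprss2 (at least 18.3-fold) were at the floor in Akt cells. Cbr3 (at least 12.1-fold), Pipox (at least 7.1-fold) and Myb (at least 6.32-fold) were at the floor in control cells.

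**Figure D3:**
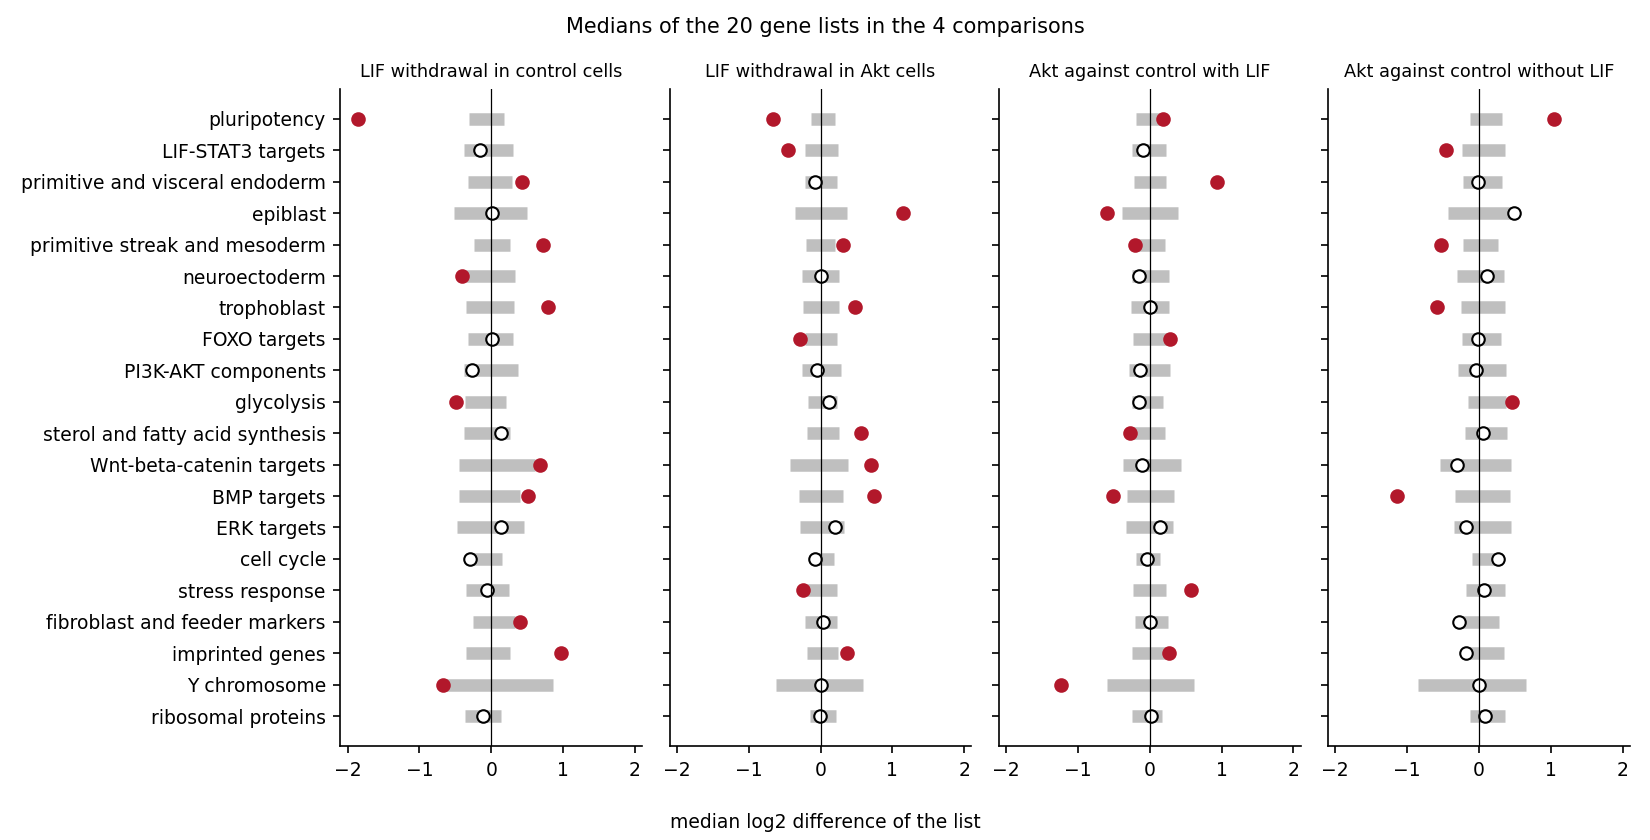
Median log2 difference (horizontal axis) of each of the 20 gene lists in the 4 comparisons, with grey bars for the central 95% of 10000 random lists matched on expression and filled points for medians outside them. Each median compares 2 single arrays. The pluripotency median is -1.85 and -0.66 after LIF withdrawal in control and Akt cells, and 0.18 and 1.04 for Akt against control cells with and without LIF.

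The limma model asked what LIF withdrawal did in both lines. With Benjamini-Hochberg adjustment, 9 genes rose and 10 fell, and 583 of 6258 had an unadjusted p under 0.05. Klf4 fell by 2.56 on the log2 scale (SE 0.324, adjusted p = 0.0165). Socs3 (-2.63), Tcl1 (-2.86), Pfkp (-2.74), Nr0b1 (-3.43), Tfcp2l1 (-2.23), the cholesterol transporter gene Abca1 (-2.11) and Mknk1 (-2.07) fell as well. Nr0b1, Abca1, Mknk1, Alox15 and Acta2 were at the floor on 1 array, so their averages include a bound. Acta1 rose by 2.96 (SE 0.361, adjusted p = 0.0165), Alox15 by 2.65, Amot by 2.34, Wnt3 by 2.22, Dab2 by 2.18, Igfbp3 by 2.16, Tagln by 2.12 and Acta2 by 2.12. Of the 30 pluripotency genes, 18 fell when adjusted over the list alone and 4 over all genes, and of the 20 LIF-STAT3 targets 5 fell adjusted over the list alone and 4 over all genes. Adjusted over the list alone, 5 of 14 trophoblast genes and 5 of 15 imprinted genes rose, and none of either over all genes. These calls rest on 1 residual degree of freedom, and 8 of 10 alternative settings called no gene, with 236 to 643 genes at an unadjusted p under 0.05.

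In the same model, Akt cells differed from control cells in both media for 39 genes, 10 higher and 29 lower, with 603 genes at an unadjusted p under 0.05. The lower genes included Tagln (log2 -3.90, SE 0.324, adjusted p = 0.00164), Acta2 (-3.72), the annexin gene Anxa3 (-3.46), Acta1 (-3.14), Ltb (-2.97), Eif2s3y (-2.72), the cadherin gene Cdh2 (-2.71) and Cnn2 (-2.68). The higher genes included Aard (2.36, adjusted p = 0.0183), Cubn (2.31), Cpt1a (2.45), Lama1 (2.17), Fbp2 (2.06), Akr1b8 (2.11), Tiparp (1.92) and Mt1 (3.69). Of these genes, Acta2, Eif2s3y, Cdh2, Cubn and Lama1 were at the floor on 1 array and Ltb and Fbp2 on 2, so their averages include bounds. The plain _at probe set of Cubn gave -0.22. Adjusted over the list alone, 6 of 23 mesoderm genes and 6 of 14 trophoblast genes were lower and 5 of 30 pluripotency genes and 5 of 20 endoderm genes higher, against 2, 0, 1 and 2 over all genes. In the other direction, 2 trophoblast genes were higher and 1 endoderm gene lower over the list alone. In 5 of 10 alternatives limma called no gene, with 263 to 553 genes at an unadjusted p under 0.05.

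The genes of each chromosome were also compared between the lines. Only chromosome 11 had medians outside the range of random gene sets in both media, 0.05 with LIF and 0.14 without over 448 genes (percentiles 98.0 and 98.9), where the median of all genes was 0.01 and 0.08. The medians furthest from 0 in a single medium were those of chromosome 13 with LIF, -0.18 over 161 genes, and of chromosome 19 without LIF, 0.16 over 186 genes (0.02 with). Chromosome 13 was at percentile 0.005 with LIF. Without LIF its median was -0.02 at percentile 2.72, just inside the range and below the median of all genes.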

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

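The tests in this part were chosen after the results were seen, although the bound for array scaling was set before the values under other scalings were seen. With 1 array per group, no group was searched for a sample far from its fellows.

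In 11 genes among those named, LIF withdrawal went at least 2-fold one way in control cells and at least 2-fold the other way in Akt cells, and the difference was not tested. The naming rule takes, among others, the genes whose responses differ most between the lines, so it favours genes of this kind. Whether they are more than independent responses would give was not worked out. The response in Akt cells minus that in control cells was -3.52 for Lgals3, -3.45 for Kdelr3, -3.41 for Hmga2, -3.21 for Bmp4 and -3.09 for Litaf, which were higher in control cells and lower in Akt cells without LIF. It was 4.54 for Pim2, 4.06 for Slc27a2, 3.92 for Dnmt3a, 3.57 for Utp14a, 3.14 for Pus1 and 2.25 for Ccne1, which went the other way. Of 789 probe sets without 1 named gene, which no comparison used, 55 were at least 2-fold higher and 44 lower after LIF withdrawal in control cells, and of 794 in Akt cells 20 were higher and 27 lower.

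More genes were at least 2-fold different after LIF withdrawal in control cells (825) than in Akt cells (396), a ratio of 2.08. Noise that strikes probe sets independently does not account for all of the differences in control cells. Probe sets of one gene moved together there with an intraclass correlation of 0.617 (95% bootstrap interval over genes 0.557 to 0.670), against 0.521 in Akt cells. The spread within a gene was larger in control cells (SD 0.411 against 0.351), so a contribution of such noise to the higher count stays open. The ratio stayed between 1.91 and 2.12 under the 3 other scalings, of which that to the hybridization controls was added after seeing the data. Each multiplies an array by a single factor, which shifts its genes together and hardly changes the spread of the differences. These scalings therefore had little room to move the ratio, and array effects that depend on intensity were not tested. The state of the single control culture without LIF, RNA quality that affects whole genes, and a weaker response of cells with active Akt cannot be separated with 1 culture per group, and no test here bears on the choice between them.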

How the results depend on the processing

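Of 1000 values of list medians under 8 alternative settings, 805 moved by less than their spread, 194 moved by more without turning a direction outside the range of the random lists, and 1 reversed, the median of Wnt-beta-catenin targets in control cells, -0.086 with a floor at the 60th percentile. Of 2954 values of named genes, 2235 stayed within the spread or past their threshold, 481 moved by more than the spread, 234 were no longer past the threshold of their test, and 4 reversed, all with only plain _at probe sets, where another probe set stands for the gene. They were Txnip in Akt cells (0.586) and Cubn with LIF (-0.115), without LIF (-0.326) and over both media (-0.221, adjusted p 0.978, against a range of 0.0092 to 0.978 over the alternatives). The ratio of the counts in control and Akt cells after LIF withdrawal ranged from 1.53 to 3.58. No array could be left out, since each group has 1 and the model would have no residual degree of freedom. The lowest came with a floor at the 25th percentile, and the highest with no floor or filter and an added constant.

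A floor at the 25th percentile, which takes in more dim genes, gave 384 genes 2-fold higher and 394 lower in Akt cells after LIF withdrawal, 380 higher and 417 lower for Akt against control with LIF, 558 higher without LIF, and 524 between control cells with LIF and Akt cells without. A floor at the 60th percentile gave 221 lower in control cells after LIF withdrawal, 69 higher and 123 lower in Akt cells, 109 higher and 105 lower for Akt against control with LIF, 189 higher and 312 lower without, and 90 in that last pair. The response was then higher in Akt cells for 346 genes and lower for 357, the correlation of the responses was 0.133, and 7.66% of the genes higher in control cells were also higher in Akt cells. With log2(value + 32) and no floor, the counts were 252 higher and 174 lower in control cells, 44 and 75 in Akt cells, 83 and 70 for Akt with LIF, 142 and 273 without, and 71 in the closest pair. The response differed for 264 and 279 genes, and the shared percentages were 5.95% of genes higher in control cells, 34.1% of those higher in Akt cells and 36.0% of those lower in Akt cells. The added constant shrinks differences of dim genes.

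Scaling to the hybridization controls, chosen after seeing the data, gave 112 higher and 343 lower in Akt cells after LIF withdrawal and 7.99% shared. It placed the median log2 difference of all genes at -0.123 for LIF withdrawal in control cells, -0.169 in Akt cells, 0.129 for Akt against control with LIF and 0.0851 without, where the corresponding values under quantile normalization were -0.0507, 0.0132, 0.0051 and 0.0776.

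The limma counts depended on the setting. For LIF withdrawal over both lines, 0 genes higher and 0 lower were called with equal trimmed means, median centring, either other floor, no floor, hybridization controls, the mean of probe sets, or no line term. Plain _at probe sets gave 11 higher and 16 lower, and a trended prior 12 higher and 20 lower. For Akt over both media, equal trimmed means gave 1 higher and 10 lower, and the lower floor 5 higher and 24 lower. The mean of probe sets gave 0 higher and 3 lower, plain _at probe sets 16 higher and 40 lower, and a trended prior 25 higher and 52 lower. The counts for Akt were 0 and 0 with median centring, the higher floor, no floor, hybridization controls and no LIF term. Unadjusted p under 0.05 was reached by 236 to 643 and 263 to 553 genes where limma called none. The prior degrees of freedom that eBayes estimated were 8.69 in the fit reported, and 10.5 and 14.4 with plain _at probe sets and a trend. They were between 2.04 and 8.32 in fits without calls for LIF withdrawal, and between 2.04 and 5.63 in those without calls for Akt. Apart from the construction of each setting named above, the cause was not tested.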

Other observations

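The 5 gene lists in this part were put together after the data had been seen, and all tests in it were chosen after that, although the bound for array scaling was set before the values under other scalings were seen. Control cells without LIF had higher levels of interferon-inducible genes. Of 23 measured, 13 were at least 2-fold higher after LIF withdrawal and none lower, with a median log2 difference of 1.15, which was 0.52 with no floor. The guanylate-binding protein gene Gbp2 had a log2 difference of 2.85, the antigen presentation genes Tapbp and B2m 2.29 and 1.85, and Isg15 and Iigp1 bounds of 2.51 and 2.63. With LIF, 6 were already at least 2-fold lower in Akt than in control cells (mean -0.47, median 0.00). In Akt cells none of the 23 was 2-fold different after LIF withdrawal, with 8 above 0, 6 below 0 and the others at 0. A gene at the floor on both Akt arrays has a difference of 0. Members could be measured through the control arrays alone, so part of this lack of a difference is built in. Without LIF, 12 were lower in Akt than in control cells, with a median of -1.37. Gbp2, Gbp2b and Gbp3 were at the floor on both Akt arrays.

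Genes of the actin cytoskeleton and targets of the transcription factor SRF were higher in control cells without LIF, 17 of 23 at least 2-fold, with a median of 1.23. Of the 23, 4 (Tagln, Acta2, Cnn1 and Ccn2) also stand on lists fixed beforehand. In Akt cells 6 were, with a median of 0.15, or 0.00 when scaled to the hybridization controls. Against control cells, Akt cells had 12 of them lower with LIF (median -1.07, or -0.33 with a floor at the 60th percentile) and 18 lower without (median -1.96). Tpm1 had log2 differences of -1.93 and -2.57 and Vcl of -0.88 and -1.96, while the cytoplasmic actin gene Actg1 had -0.20 and -0.15. Among 5 metallothionein and zinc transporter genes, with a median of -0.71 in control cells, Mt1 went from 646.5 to 50.9 and Mt2 from 1684.5 to 283.9 in control cells after LIF withdrawal, and lay between 2172.1 and 3171.3 on the Akt arrays. Of 5 hedgehog targets, whose median in control cells was 0.02, Ptch1 and Gli1 had log2 differences of -4.29 and -1.85 (the latter a bound) after LIF withdrawal in control cells and 0.64 and 0.20 in Akt cells, although a second probe set of Ptch1 gave 0.06 in control cells.

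Targets of ATF4, the transcription factor of the amino acid and unfolded protein responses, were higher in Akt cells with LIF than in control cells with LIF, with 13 of 29 at least 2-fold higher, none lower and a median of 0.72. The higher genes included Cars (2.20), Nars (1.38) and Mthfd2 (1.23), 5 of the 29 (Asns, Atf5, Trib3, Ddit3 and Herpud1) repeat members of the stress response list, and in Akt cells 10 of the 29 were at least 2-fold lower without LIF than with it. The lowest median under the 3 other scalings, 1 of them added after seeing the data, was 0.702. Each of them multiplies an array by a single factor, and the median of all genes reached at most 0.129 under them. They could therefore hardly have removed the excess, and they do not test an array effect that depends on intensity. Active Akt as the only cause and the state of the single Akt culture with LIF cannot be told apart, because only 1 culture stands for each medium. The excess was 0.367 without LIF, and the median over genes of the excess with LIF minus that without was 0.381 (bootstrap interval over genes 0.184 to 0.946), which could follow from either.

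Eif2s3y, on the Y chromosome, is read by a probe set that may also detect related genes, and had quantile normalized intensities, before the floor was set, of 134.6 and 84.1 in control cells with and without LIF and 16.5 and 14.8 in Akt cells. A candidate explanation is that the Akt line has lost the Y chromosome. Of the 8 other Y-linked probe sets, only 1, that of Uty, was more than 2 times the floor in control cells, at 37.1 with LIF, but it was under the floor without LIF (15.4) as in Akt cells (6.0 and 8.0). A probe set of Uba1y was at 25.1 and 8.5 in control cells and at 11.5 and 16.2 in Akt cells, the last just above the floor, and the others were too low to decide, so loss of the chromosome cannot be told apart from lower expression of these genes.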
